A study of Mus musculus with 26 samples.

How the data were processed

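ATAC-seq peak lists of D1 and D2 MSN nuclei from mouse brain were used, 1 list for each of 8 groups that together hold 26 libraries (1 to 8 per group). The processing notes of the authors name cutadapt, HISAT, SAMtools and MACS2, without versions or roles, and the build mm10. Whether libraries were pooled before peaks were called is not stated. The fold enrichment of each peak, a ratio over the background of the peak caller, was deposited by the authors and is not scaled between lists. It was therefore compared only within a list, apart from the fixed cut at a fold of 6 given below. The q-value of each peak, also by the authors and on a linear scale, reached 0.0453 at most. The lists hold no column per library (0 such columns), so no replicate error, no paired comparison and no p-value between groups could be had.

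Peaks on chromosomes 1 to 19, X and Y were used, and no peaks within a list overlapped. The smallest peak was 200 bp wide. For each list the number of peaks, the covered length, the widths and the share within 1 kb of a TSS (the authors' distance and classes, with limits of 250, 1000 and 3000 bp) were computed. Read totals are not in the lists. The background pileup was solved from the spacing of the fold values, taking the fold of MACS2 as pileup plus 1 over background plus 1, and it sets the precision of each list. Shares have exact Clopper-Pearson intervals at 95% confidence.

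Comparisons were SC, CS and CC against SS, and CC against SC and CS, within each cell type, and D1 against D2 within each state, 14 in all. A peak was found in the other list when it shared at least 1 bp. The strongest 10000 peaks by q were also searched in the other list. For gene lists, the bp covered over the gene body plus 5 kb upstream were divided by the total of the list over 21883 protein-coding genes. The log2 ratio used a pseudocount of 200 bp, and the median over a gene list was placed as a percentile among 10000 random lists of the same size, matched on length and mean coverage. Percentiles below 2.5 or above 97.5 were taken as outside. Ties with random lists were counted by mid-rank, so a marker list with few covered members can be drawn to the middle percentile. Percentiles of 18 lists per comparison are descriptions of these peak lists and were not corrected for multiple comparisons.

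The 18 gene lists were D1 MSN, D2 MSN, pan-MSN, rapid immediate-early, delayed activity-regulated, glutamate receptors, dopamine and cAMP signalling, ion channels, synaptic adhesion, cocaine-linked regulators, H2A.Z machinery, housekeeping, astrocyte, oligodendrocyte lineage, microglia, vascular, striatal interneuron and cortical excitatory neuron. All 230 genes were found. The last 6 lists hold 61 markers of other cell types. Gene positions came from a RefSeq table of the same build, and strand, absent there, from the annotation in the peak lists, which lacked it for 6928 genes. For these 6928 genes, 5 kb on both sides of the gene body were counted in place of 5 kb upstream. Of 14546 symbols in both, 99.8% overlapped in position.

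Named peaks follow a rule: in each direction of a comparison, among peaks with no peak of the other list within 1 kb, on autosomes and X, in a protein-coding gene body or within 1 kb of its TSS, the 10 with the highest fold, 1 per gene. Drd1, Drd2, members of the D1 MSN, D2 MSN and rapid immediate-early lists and members of lists outside the percentile limits could also be named. Gene lists, comparisons, this rule and most alternatives were fixed before the data were examined.

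Alternatives were a q of at most 1e-05, autosomes only, a reciprocal overlap of 50%, a peak within 1 kb, lists of equal length (the strongest 27917 peaks by q), the strongest 5000 peaks, ranking by fold, promoters within 2.5 kb, a pseudocount of 1000 bp, and the gene body plus 50 kb on each side. A fold of at least 6 in the shorter list and comparisons within a technical set alone were added after the data were seen. The technical sets were assigned by peaks on patch scaffolds, not by the labels, and chromosome shares were used to describe them. Results of some genes are not reported here. Motif shares and a split of gene bodies into exons and introns were not analysed here.

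The steps were tested on simulated data: 10 of 10 simulated overlaps were recovered, 2 of 100 unshifted gene lists lay above percentile 97.5, and 81 of 100 lists of 12 genes shifted by 1 SD did. The simulated gene values held no ties, unlike the real ones. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.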

Results

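Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in nuclei of mouse medium spiny neurons (MSNs), the principal neurons of the striatum. The labels give the tissue as brain, and the series title places the study in the nucleus accumbens. D1 and D2 MSNs, which carry the dopamine receptors Drd1 and Drd2, were profiled in 4 states: baseline (SS), acute cocaine (SC), chronic cocaine followed by a long withdrawal (CS) and cocaine relapse (CC). The 26 libraries divide into 2 D1 SS, 4 D1 SC, 4 D1 CS, 4 D1 CC, 2 D2 SS, 1 D2 SC, 8 D2 CS and 1 D2 CC. Each group has 1 peak list, so no value below has a replicate error, no p-value between groups can be given, and every difference describes these lists. Intervals are exact 95% binomial (Clopper-Pearson) intervals that cover counting error only.

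The D1 CC list was the longest, with 77103 peaks over 42.3 Mb, against 28579 peaks over 14.2 Mb in D1 SS, 28321 over 13.9 Mb in D1 SC and 48469 over 24.9 Mb in D1 CS. Among the D2 lists, D2 CS was the shortest with 27917 peaks over 13.7 Mb, while D2 SS held 61818, D2 SC 58810 and D2 CC 68444. Read totals per library were not used here. The spacing of the authors' fold values gave a background pileup of 4.12 reads in D1 SS, 1.15 in D1 SC, 3.5 in D1 CS and 4.23 in D1 CC, and of 6.14, 4.48, 2.22 and 5.85 in D2 SS, SC, CS and CC. Among the frequent fold values of peaks at that background, the lowest was 4.19 in D1 SC, the shallowest list, and 2.80 in D2 SS, the deepest. Weak sites were therefore least detectable in D1 SC. Promoter peaks, within 1 kb of a transcription start site (TSS), made up 49.97% (49.4 to 50.6%) of D2 CS and 47.0% (46.4 to 47.5%) of D1 SC, but 24.1% (23.8 to 24.4%) of D1 CC and 23.3% (23.0 to 23.6%) of D2 CC. Among the strongest 27917 peaks of each list, the shares were 42.3% in D1 CC and 36.4% in D2 CC.

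**Figure D1:**
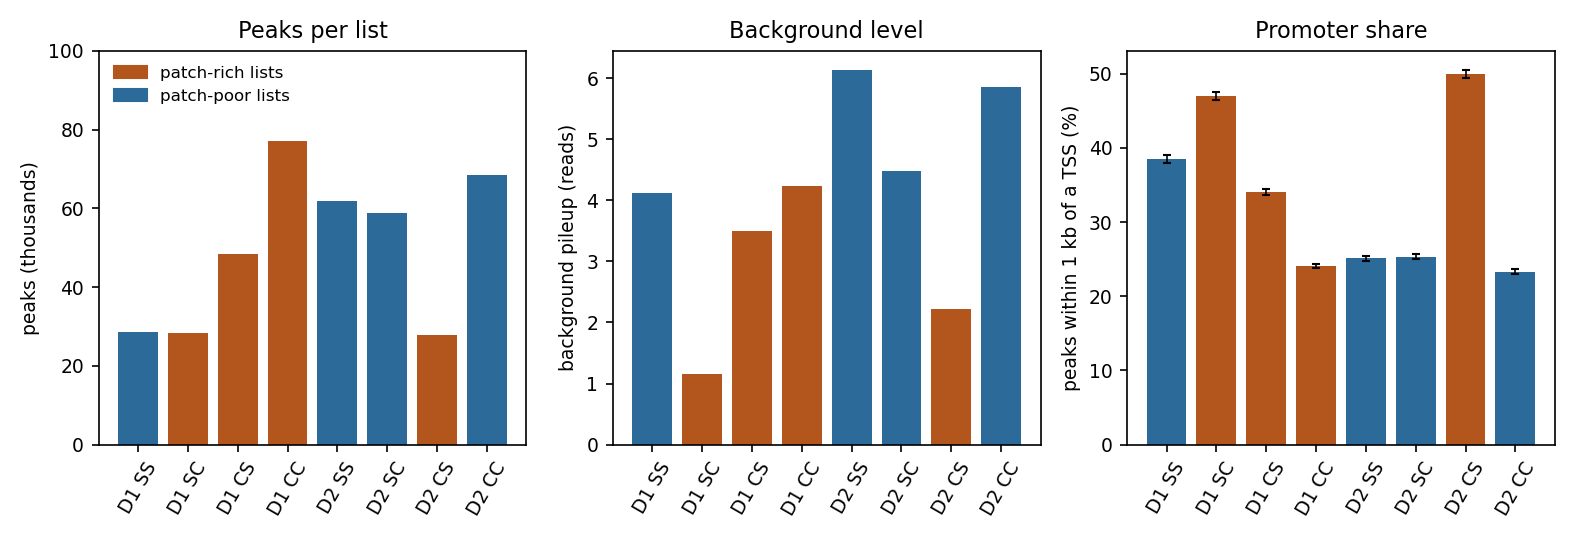
Bars give, for each of the 8 peak lists, the peaks in units of 1000, the background pileup in reads and the percentage of peaks within 1 kb of a TSS (error bars: 95% Clopper-Pearson intervals). D1 CC holds 77103 peaks at a background of 4.23 reads, while D1 SS holds 28579 at 4.12, and the promoter share is 49.97% in D2 CS and 23.3% in D2 CC (36.4% at equal list length).

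The lists split on a feature that matches neither cell type nor state, but follows the number of libraries and the order in which the labels list them. D1 SC, D1 CS, D1 CC and D2 CS held 74, 115, 144 and 71 peaks on patch scaffolds, the alternate sequences added to the mouse assembly, and are called patch-rich here. D1 SS, D2 SS, D2 SC and D2 CC held 4, 7, 7 and 7 and are called patch-poor. The patch-poor groups have 1 or 2 libraries each and are listed first in the labels, and the patch-rich groups have 4 or 8. Chromosome 7 had 1.16 to 1.31 times as many peaks as chromosome 18 in the patch-rich lists and 0.73 to 0.80 times as many in the patch-poor ones. With each list reduced to its strongest 27917 peaks, lists of the same set shared 76.6 to 87.9% of peaks (median 80.8%, 12 pairs) and lists of different sets 69.9 to 78.2% (median 72.8%, 16 pairs). Within a set, lists of the same cell type shared a median of 85.8% (80.2 to 87.9%) and lists of different cell types 79.7% (76.6 to 81.5%). Every within-set pair of different cell types includes D1 SS or D2 CS, so this difference rests on those lists. Across sets, the medians were 72.7% for the same cell type (6 pairs) and 73.2% for different cell types (10 pairs). Comparisons of D1 SC, CS or CC with D1 SS, of D2 CS with D2 SS or D2 CC, and of D1 with D2 in SC and CC run across the 2 sets, so technical set and group cannot be told apart in them.

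**Figure D2:**
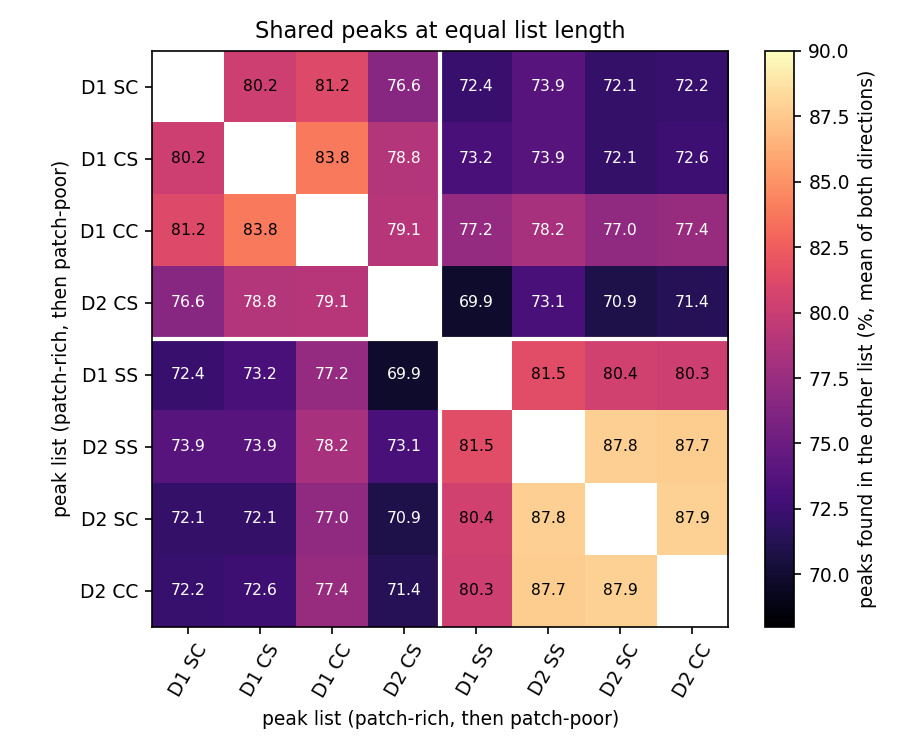
The matrix gives, for each pair of lists at equal length (27917 peaks), the percentage of peaks that overlap the other list by at least 1 bp, as the mean of both directions. White lines divide the patch-rich from the patch-poor lists: pairs within a block share 76.6 to 87.9%, pairs across blocks 69.9 to 78.2%.

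Regions near Drd1 and Drd2 were among the few that separated all D1 from all D2 lists, although Drd1 itself held a promoter peak in all 8 lists and Drd2 a peak in every list except D1 SS. Merging the 8 lists gave 94493 regions, of which 17243 were in every list and only 5 lay in every D1 list and no D2 list. Of those 5, singled out after their values were seen, 3 lay 105 to 141 kb from Drd1 on chromosome 13 (53909778 to 53910452, 53923656 to 53924440 and 53945593 to 53946311, mm10), 1 lay 8.48 kb from Chst2 on chromosome 9 and 1 lay 40.8 kb from P2ry2 on chromosome 7. A further 35 regions were in every D2 list and no D1 list, and 5 of them lay within 150 kb of Drd2 on chromosome 9: 49300720 to 49301049, 49307562 to 49308265, 49408292 to 49408882, 49409257 to 49409828 and 49490045 to 49490753. The other D2 regions included promoter peaks of Camsap2, a microtubule-binding protein, and Nipal4, and gene-body peaks in the adhesion genes Cntn4 and Opcml, in Ctnna2 and in Ppargc1b, a transcriptional coactivator. In all, 17 of the 35 lay in gene bodies and 14 were intergenic. Of the 35 ways to divide the 8 lists into 4 and 4, 14 separated more regions than the 40 of the cell types. The division of the 4 shortest from the 4 longest lists separated 6825 and that of the technical sets 661.

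The question for each pair of states is which genes and regions carry open chromatin in one and not in the other. For D1 SC against D1 SS, acute cocaine against baseline, D2 MSN marker genes held peaks in SC that SS lacked. A peak lay in 8 of the 10 markers in D1 SC and in 1, the enkephalin gene Penk, in D1 SS. Drd2 had 2 peaks over 518 bp, the opioid receptor gene Oprd1 936 bp and the transcription factor gene Sp9 548 bp in SC, and none of them had a peak in SS. The list's median log2 ratio of covered share was 1.5, at percentile 100 of matched random lists. Synaptic adhesion genes were less covered in SC in 13 of 15 cases (median log2 ratio -0.90, percentile 0.02), with Ptprd at 2844 against 8218 bp and Lrrtm4 at 1542 against 4813 bp.

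Delayed activity-regulated genes also had lower shares in D1 SC in 13 of 15 cases (median -0.33, percentile 0.03), among them the neurotrophin gene Bdnf at 221 against 496 bp. D1 MSN markers were lower in 7 of 10 (median -0.29, percentile 1.31), among them Zfp521 at 594 against 2023 bp, although Drd1 had 1116 bp in SC and 940 bp in SS. Astrocyte markers lay at percentile 0.10, with Aqp4 and Gfap at 233 and 254 bp in SS and no peak in SC. Rapid immediate-early genes lay at percentile 84.8, 9 of 16 higher in SC and 6 lower. Fos had 504 bp in SC and no peak in SS, and Arc had 1106 against 591 bp.

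Of the D1 SC peaks, 73.5% (73.0 to 74.0%) were found in D1 SS, and 70.7% (70.1 to 71.2%) of the D1 SS peaks in D1 SC. Peaks of SC missing from SS lay at promoters in 38.7% of cases, and peaks of SS missing from SC in 8.93%. For peaks found in the other list, the promoter share was 49.95% in SC and 50.8% in SS. Strong peaks of SC with no SS peak within 1 kb lay at the zinc finger gene promoters Zfp433 (chromosome 10, 81704421 to 81705274, fold 13.9), Zfp97 (chromosome 17, 17120792 to 17121681, fold 13.3) and Zfp781 (fold 12.3), at the promoters the authors assign to Srp54a and Srp54b (Gm2436 and Gm2446 in the gene table), signal recognition particle genes, and in Gnb1l (fold 14.1). Strong peaks in the other direction lay within the bodies of the neuregulin receptor gene Erbb4 (chromosome 1, 68451783 to 68452478, fold 7.88), Dpp10, Sema3a, Lcorl and Adgrv1. Of the 10 peaks named for SS, 6 were in every list except D1 SC. Of the 10 peaks named for SC, 9 were held by exactly the 4 patch-rich lists, so technical set and cocaine cannot be told apart here. With 50 kb on each side of the gene body counted, the delayed genes lay at percentile 4.77 and the astrocyte markers at 87.9.

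After chronic cocaine and withdrawal, the D1 list again covered D2 MSN markers that D1 SS lacked, 9 of 10 against 1 (median log2 ratio 1.28, percentile 99.98). Drd2 held 1585 bp, the glutamate receptor gene Grik3 1605 bp and Oprd1 1317 bp in D1 CS. Oligodendrocyte lineage markers had a peak in 10 of 11 cases against 4 (percentile 98.1), including small peaks at Mog (395 bp), Mag (409 bp) and Mobp (246 bp), and 41 of the 61 markers of other cell types had a peak in CS against 19 in SS. The remaining lists of such markers lay inside the limits, from percentile 29.9 for astrocyte to 71.6 for striatal interneuron markers. D1 MSN markers were lower in 9 of 10 (median -0.49, percentile 1.5), synaptic adhesion genes in 13 of 15 (median -0.49, percentile 1.38) and delayed activity-regulated genes in 12 of 15 (median -0.50, percentile 1.22). Fos had 1055 bp in CS and no peak in SS, and the rapid immediate-early genes lay at percentile 95.2, 8 higher in CS and 8 lower.

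In D1 CS, 86.9% (86.5 to 87.3%) of the D1 SS peaks were found, and 52.0% (51.5 to 52.4%) of the D1 CS peaks were found in D1 SS. Strong CS peaks with none in SS lay at the promoters of Zfp97 (fold 12.9), Srp54a (12.5), Srp54b (12.4) and Dgcr8 (11.6), a gene of microRNA processing, and all 10 named peaks were held by exactly the patch-rich lists. Strong SS peaks with none in CS lay in the bodies of Cntn4 (chromosome 6, 106571825 to 106572245, fold 7.47), Aff2, Pcdh9 and the progesterone receptor gene Pgr. Because the pair crosses technical sets, set and withdrawal state cannot be separated. With lists of equal length, the D2 markers lay at percentile 92.8, the oligodendrocyte markers at 50 and the delayed genes at 3.66. The value of 50 can arise from ties alone and tells little about the oligodendrocyte markers.

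In relapse, the D1 list held peaks in all 10 D2 MSN markers (median log2 ratio over SS 2.26, percentile 100), with Drd2 at 2554 bp, Gpr6 at 1581 bp, Six3 at 1872 bp and Adora2a, the adenosine receptor gene typical of D2 MSNs, at 494 bp. None of these 4 genes had a peak in D1 SS. Delayed activity-regulated genes took lower shares in 13 of 15 cases (median -0.76, percentile 1.99), even where their bases were more, as at Homer1 with 2856 against 1719 bp. Of the 61 markers of other cell types, 50 had a peak in CC and 19 in SS. Their 6 lists lay inside the percentile limits, from 10.95 for astrocyte to 94.5 for microglia markers, so matched random lists rose similarly. D1 CC contained 97.4% (97.3 to 97.6%) of the D1 SS peaks, while 35.5% (35.1 to 35.8%) of the D1 CC peaks were found in D1 SS.

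Of the 49765 D1 CC peaks missing from D1 SS, 36.7% were found in D1 CS and 12.4% in D1 SC, and 51.7% in D2 SS, 47.0% in D2 SC and 58.6% in D2 CC. Promoters of Zfp97 (chromosome 17, 17120758 to 17121750, fold 15.3), Zfp781 (fold 14.2), Zfp53 (fold 13.4) and the mitochondrial carrier gene Slc25a53 (fold 12.2) were among the strong CC peaks with none in SS, and 7 of the 10 named were held by exactly the patch-rich lists. Another 3 were in every list except D1 SS. Only 588 SS peaks had no CC peak within 1 kb. They included peaks in Ddx60 (fold 5.86), Csmd3 and Dach1. One in the dopamine transporter gene Slc6a3 (chromosome 13, 73540579 to 73540778, fold 4.68), of the smallest width in any list, was in no other list. Of the 10 peaks named for SS, 5 were held by exactly the patch-poor lists. The pair crosses technical sets, and at equal list length the D2 markers lay at percentile 19.9, and with 50 kb on each side counted the delayed genes lay at 4.61.

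**Figure D3:**
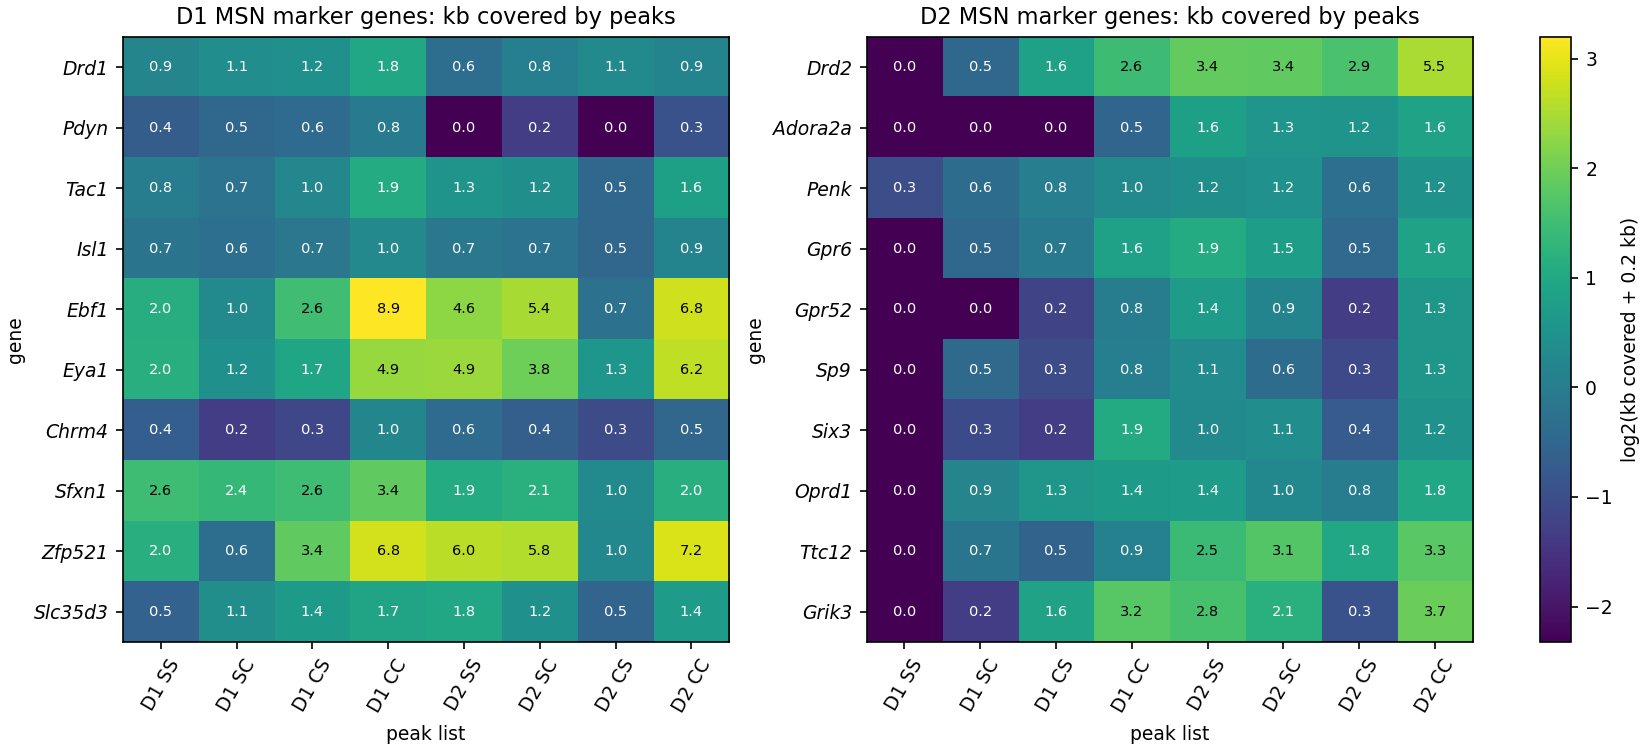
Each cell gives the kb covered by peaks over a gene body plus 5 kb upstream for 10 D1 MSN markers (left) and 10 D2 MSN markers (right) in each peak list, with colour on a log2 scale. D1 SS covers only Penk among the D2 markers, while D1 CC and all 4 D2 lists hold a peak in each of the 10.

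Relapse against acute cocaine in D1 MSNs compares lists of the same technical set. D2 MSN markers took higher shares in CC in 6 of 10 cases (median 0.52, percentile 99.95), with Adora2a at 494 bp and Gpr52 at 812 bp against no peak in SC, and Grik3 at 3198 against 200 bp. Synaptic adhesion genes were higher in 14 of 15 (median 0.78, percentile 97.4), and glutamate receptor genes in 14 of 15 (median 0.69, percentile 93.1). Rapid immediate-early genes had a median of -0.12 yet lay at percentile 99.89, because matched random lists had lower medians still. Only 4 of the 16 took a higher share in CC, such as Egr3 with 2674 against 568 bp, and 12 a lower one, such as Nr4a3 with 2220 against 1545 bp. Markers of other cell types had a peak in 50 of 61 cases in CC and 18 in SC. Medians were 1.2 for astrocyte (9 of 10 higher, percentile 84.0) and 1.35 for vascular markers (percentile 82.2). All 6 lists of these markers lay inside the limits, from percentile 47.5 to 94.8.

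D1 CC contained 98.9% (98.7 to 98.97%) of the D1 SC peaks, and 33.8% (33.5 to 34.1%) of the D1 CC peaks were found in D1 SC. Of the 51032 CC peaks missing from SC, 34.4% were found in D1 CS, and 54.5% in D2 SS, 50.4% in D2 SC and 61.2% in D2 CC. Strong CC peaks with none in SC lay at the promoter of the coat protein gene Copb1 (chromosome 7, 114254035 to 114255039, fold 10.9) and in the bodies of Ccbe1 (chromosome 18, 66123584 to 66124258, fold 10.3), Spag16, Ptprd, Cntn4 and Shtn1. Of the 10 peaks named for CC, 5 were in every list except D1 SC, the list with the lowest background. SC peaks with none in CC numbered 205, including those in Aig1 (fold 7.21), Mphosph8 (7.14), Stxbp4 (6.52) and the transcription factor gene Zfp423 (6.02). Among equally long lists, the D2 markers turned to percentile 0.24 and the immediate-early genes lay at 61.8.

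Relapse against withdrawal in D1 MSNs, again within a technical set, showed synaptic adhesion genes at higher shares in CC in 14 of 15 cases (median 0.55, percentile 99.8), such as Tenm2 with 25774 against 11291 bp and Nlgn1 with 19620 against 6497 bp. D1 MSN markers (median 0.17, percentile 98.5) and D2 MSN markers (median 0.38, percentile 100) were both higher, with Ebf1 at 8939 against 2635 bp and Six3 at 1872 against 200 bp. For rapid immediate-early genes the value lay at percentile 98.9 with a median of -0.18. Of the 16, 6 took a higher share in CC, such as Nr4a2 with 2400 against 991 bp, and 10 a lower one, such as Npas4 with 2141 against 2040 bp. Other cell type markers had a peak in 50 of 61 cases in CC and 41 in CS. The 6 lists of these markers lay inside the limits, from oligodendrocyte lineage markers at percentile 18.8 to striatal interneuron markers at 85.2.

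D1 CC contained 93.5% (93.3 to 93.8%) of the D1 CS peaks, and 55.1% (54.8 to 55.5%) of the CC peaks were found in CS. CC peaks with none in CS lay in Sntg1 (chromosome 1, 8496060 to 8496820, fold 9.54), the adhesion gene Cadm2 (chromosome 16, 67373325 to 67374048, fold 9.18), the calcium channel gene Cacna2d1 (fold 8.61) and the cAMP phosphodiesterase gene Pde4d (fold 8.09). CS peaks with none in CC lay in Dync1i1 (fold 6.09), Lmbrd1 (6.07, in no other list) and Cenpe (5.56). At equal list length the D1 markers stayed at percentile 98.9, while the adhesion genes lay at 71.2, the D2 markers at 61.8 and the immediate-early genes at 88.3.

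In D2 MSNs, acute cocaine and baseline share a technical set and gave similar lists: 87.1% (86.8 to 87.4%) of the D2 SC peaks were found in D2 SS and 82.1% (81.8 to 82.4%) of the D2 SS peaks in D2 SC. The promoter of Nr4a2, an immediate-early nuclear receptor gene, held a peak in SS (chromosome 2, 57123528 to 57124449, fold 6.02) with none in SC within 1 kb, and Nr4a2 had 2263 bp covered in SS and 653 bp in SC. Promoter peaks of Psd4 (fold 5.56) and Ighmbp2 (5.18) and a peak in the cGMP kinase gene Prkg1 (5.46) were also in SS and not in SC. SC held peaks with none in SS in Npepps (chromosome 11, 97207100 to 97207403, fold 6.20), Csmd1 (6.02), the AMPA receptor gene Gria3 (5.84), Sema3a (5.84) and Cntn4 (5.84).

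Synaptic adhesion genes took higher shares in D2 SC in 12 of 15 cases (median 0.15, percentile 99.5), with Tenm2 at 24428 against 22554 bp. D2 MSN markers were lower in 6 of 10 (median -0.17, percentile 0.71), including Sp9 at 578 against 1060 bp, while Drd2 had 3387 against 3444 bp. Cortical excitatory neuron markers were lower in 6 of 10 (percentile 0.15), among them Tbr1, with 487 bp in SS and no peak in SC. Rapid immediate-early genes lay at percentile 39.9, with Fos at 1045 against 803 bp and Egr4 at 989 against 1340 bp. With lists of equal length, the D2 markers lay at percentile 92.8, the adhesion genes at 90.7 and the cortical markers at 49.9. The value of 49.9 can arise from ties and tells little about the cortical markers. D2 SC comes from 1 library.

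After withdrawal, the D2 list held 27917 peaks against 61818 in D2 SS, with 49.97% against 25.1% of them at promoters (37.8% in D2 SS at equal list length). Synaptic adhesion genes took lower shares in 14 of 15 cases (median -1.13, percentile 0.525), as at Ptprd with 2187 against 25508 bp and Tenm2 with 5435 against 22554 bp. All 15 ion channel genes were lower (median -0.74), although matched lists were too (percentile 19.3). D2 MSN markers lay at percentile 1.35 (median -0.11), with Grik3 at 328 against 2824 bp but Drd2 at 2867 against 3444 bp. For rapid immediate-early genes the value lay at percentile 0.10 with a positive median of 0.08, since matched lists were higher.

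D2 SS contained 93.7% (93.4 to 93.9%) of the D2 CS peaks, and 38.3% (37.96 to 38.7%) of the D2 SS peaks were found in D2 CS. SS peaks with none in CS lay in the DNA polymerase gene Pola1 (chromosome X, 93310114 to 93310972, fold 11.6), the potassium channel gene Kcnh7 (fold 9.39), St8sia6 (9.87) and Il1rapl2 (9.56). Of the 10 peaks named for SS, 7 were in every list except D2 CS. CS peaks with none in SS lay at Zfp97 (fold 12.4), Srp54b (12.5), Zfp433 (10.7) and the mitotic kinesin gene Kif11 (chromosome 19, 37375859 to 37376576, fold 10.6), and all 10 named were held by exactly the patch-rich lists. Technical set and state are therefore confounded in this pair. Among equally long lists, the D2 markers lay at percentile 38.9 and the immediate-early genes at 15.3, while the adhesion genes stayed at 0.40.

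Relapse against baseline in D2 MSNs, within a technical set, gave higher shares for glutamate receptor genes in 13 of 15 cases (median 0.17, percentile 99.3), with Grm7 at 18997 against 14356 bp and Grm8 at 12769 against 9169 bp. D1 MSN markers were higher in 7 of 10 (median 0.14, percentile 99.2), among them the dynorphin gene Pdyn, with 328 bp in CC and no peak in SS. D2 MSN markers were higher in 6 of 10 (median 0.11, percentile 97.6), with Drd2 at 5462 against 3444 bp. Rapid immediate-early genes lay at percentile 64.0, 6 of 16 higher in CC and 9 lower, with Fosb among the higher at 1643 against 1149 bp.

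D2 CC contained 89.4% (89.2 to 89.6%) of the D2 SS peaks, and D2 SS contained 80.05% (79.7 to 80.3%) of the D2 CC peaks. CC peaks with none in SS lay in the bodies of Ccser1 (chromosome 6, 61879645 to 61880440, fold 6.32), the calcium-dependent phosphodiesterase gene Pde1c (6.13), Cdyl (6.09) and Pcdh15 (5.84). SS peaks with none in CC lay at promoters of the cell cycle inhibitor gene Cdkn2c (chromosome 4, 109666547 to 109667192, fold 5.32) and the heterochromatin protein gene Cbx5 (5.04), and in the transcription factor genes Mef2c (4.86) and Gli3 (4.77). Of the 13657 CC peaks missing from SS, 30.1% were found in D2 SC and 45.1% in D1 CC. At equal list length the glutamate receptor genes turned to percentile 0.275, the D1 markers lay at 47.3 and the D2 markers at 95.4, and D2 CC comes from 1 library.

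Relapse against acute cocaine in D2 MSNs set ion channel genes higher in CC in 13 of 15 cases (median 0.15, percentile 98.1), with the calcium channel gene Cacna1c at 16888 against 9866 bp and Scn8a at 6577 against 3712 bp. D2 MSN markers lay at percentile 97.4 and rapid immediate-early genes at 46.1, 7 of 16 higher in CC and 9 lower. Nr4a2, among the higher, had 1666 bp in CC and 653 bp in SC. D2 CC contained 91.7% (91.5 to 91.9%) of the D2 SC peaks, and D2 SC 77.3% (77.0 to 77.7%) of the D2 CC peaks. CC peaks with none in SC lay in the transcription factor gene Tead4 (chromosome 6, 128245979 to 128246564, fold 6.86), the imprinted gene Snrpn (6.13) and Rit2 (6.1), and SC peaks with none in CC in Slco5a1 (chromosome 1, 12920676 to 12920979, fold 6.38) and at promoters of the ATP-gated channel gene P2rx7 (5.65) and Fcgr3 (5.65). With lists of equal length, the ion channel genes lay at percentile 4.99, and each list comes from 1 library.

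Relapse against withdrawal in D2 MSNs crosses technical sets. Synaptic adhesion genes were higher in CC in 14 of 15 cases (median 1.27, percentile 99.89), with Cntnap2 at 27143 against 4101 bp and Ptprd at 31896 against 2187 bp. All 15 ion channel genes were higher (median 0.85, percentile 88.7). D1 MSN markers (median 0.35, percentile 98.0) and D2 MSN markers (median 0.19, percentile 99.3) were higher, as at Ebf1 with 6821 against 651 bp and Grik3 with 3677 against 328 bp, while rapid immediate-early genes lay at percentile 92.4 with 10 of 16 lower.

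D2 CC contained 94.1% (93.9 to 94.4%) of the D2 CS peaks, and 34.7% (34.4 to 35.1%) of the CC peaks were found in CS. CC peaks with none in CS lay in Il1rapl2 (chromosome X, 137678930 to 137679701, fold 10.97), Pola1 (10.7), Niban1 (10.4) and Kcnh7 (10.1), and CS peaks with none in CC at the same patch-rich promoters as against SS, Zfp97 and Srp54b among them. Of the 10 peaks named for CC, 8 were in every list except D2 CS. Set and state are confounded here. Among equally long lists, the D1 markers lay at percentile 67.1, the D2 markers at 69.1 and the adhesion genes at 97.4.

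Between cell types at baseline, within a technical set, all 10 D2 MSN markers took lower shares in D1 SS (median -2.69, percentile 0.00). Drd2 had 3444 bp in D2 SS, Ttc12 2502 bp and Adora2a 1567 bp, and none had a peak in D1 SS. D1 MSN markers were higher in D1 in 6 of 10 (median 0.48, percentile 97.3), with Drd1 at 940 against 603 bp and Pdyn at 421 bp against no peak. Housekeeping genes were higher in D1 in 13 of 15 (median 0.68, percentile 98.3). Rapid immediate-early genes were higher in D1 in 10 of 16 and lower in 5 (median 0.28), at percentile 17.7, and Fos had no peak in D1 SS against 803 bp.

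D2 SS contained 98.1% (98.0 to 98.3%) of the D1 SS peaks, and 44.2% (43.8 to 44.6%) of the D2 SS peaks were found in D1 SS. D2 peaks with none in D1 lay at promoters of Pnp2 (chromosome 14, 50955825 to 50956745, fold 9.22), the oxysterol-binding protein gene Osbpl9 (9.02) and the cell cycle inhibitor gene Cdkn2a (8.81), and 7 of the 10 named were in every list except D1 SS. D1 peaks with none in D2 numbered 426, among them peaks in Apool (fold 5.47), Slc6a3 (4.68) and the RNA-binding protein gene Khdrbs2 (4.66). At equal list length the D2 markers stayed at percentile 0.00, the D1 markers lay at 100 and the housekeeping genes lay at 91.0.

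After acute cocaine, D2 MSN markers were again lower in D1, in 8 of 10 cases (median -1.0, percentile 0.00). Adora2a and Gpr52 had no peak in D1 SC and 1279 and 929 bp in D2 SC, and Drd2 had 518 against 3387 bp. Synaptic adhesion genes were lower in D1 in 14 of 15 (median -1.21, percentile 0.04) and glutamate receptor genes in 12 of 15 (median -1.0, percentile 0.76), as at Grm8 with 881 against 9734 bp. D1 MSN markers lay at percentile 72.0. Rapid immediate-early genes were higher in D1 in 9 of 16 (median 0.19), at percentile 2.51 since matched lists were higher, and at 76.8 at equal list length. D2 SC contained 92.7% (92.3 to 93.0%) of the D1 SC peaks, and D1 SC 41.9% (41.5 to 42.3%) of the D2 SC peaks, with strong missing peaks in Lhfpl1 (chromosome X, 145298831 to 145299509, fold 10.9), Erbb4 (10.4) and Dkk2 (10.3). Of the 10 D2 SC peaks named, 4 were in every list except D1 SC. The pair crosses technical sets, and at equal list length the D2 markers lay at percentile 3.65 and the glutamate receptor genes at 7.30.

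After withdrawal, within a technical set, D1 MSN markers were higher in D1 in 6 of 10 cases (median 0.35, percentile 98.1), with Pdyn at 563 bp against no peak. D2 MSN markers were lower in 8 of 10 (median -0.30, percentile 33.2), with Adora2a at 1244 bp in D2 CS and no peak in D1 CS. Rapid immediate-early genes lay at percentile 99.86 (median 0.07), with Junb at 1755 against 237 bp. Oligodendrocyte lineage markers had peaks in 10 of 11 cases in D1 and 5 in D2 (median 0.87, percentile 99.6), with Mog, Mag and Mobp covered in D1 CS alone of the pair.

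D1 CS contained 93.7% (93.5 to 94.0%) of the D2 CS peaks, and 50.2% (49.7 to 50.6%) of the D1 CS peaks were found in D2 CS. D1 peaks with none in D2 lay in Lmcd1 (chromosome 6, 112283969 to 112284597, fold 8.94), the calcium channel gene Cacna1e (8.30) and the GABA-A receptor gene Gabra2 (8.30), and D2 peaks with none in D1 in the netrin receptor gene Unc5c (chromosome 3, 141565388 to 141565615, fold 7.41) and Slamf1 (6.39) and near Nkx2-9 (6.50). Of the 10 D1 CS peaks named, 4 were in every list except D2 CS, and of the 10 D2 CS peaks, 1 was in every list except D1 CS. With lists of equal length, the D2 markers lay at percentile 0.00, the D1 markers at 70.5, the immediate-early genes at 78.5 and the oligodendrocyte markers at 50. Ties alone can give the value of 50, which tells little about the oligodendrocyte markers.

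In relapse, D2 MSN markers were lower in D1 in 9 of 10 cases (median -0.58, percentile 0.00), with Drd2 at 2554 against 5462 bp and Adora2a at 494 against 1627 bp. Glutamate receptor genes were lower in D1 in 12 of 15 (median -0.42, percentile 0.31), delayed activity-regulated genes in 11 of 15 (median -0.21, percentile 0.53) and synaptic adhesion genes in 10 of 15 (median -0.36, percentile 1.02), as at Ptprd with 18274 against 31896 bp. For rapid immediate-early genes the value lay at percentile 97.8 (median 0.05), with Fos at 1253 against 734 bp. Microglia markers lay at percentile 99.7, Csf1r having 900 against 223 bp and Spi1 1274 against 608 bp, and D1 MSN markers at 96.2. Of the 61 markers of other cell types, 50 had a peak in D1 and 34 in D2. Astrocyte, vascular and striatal interneuron markers lay at percentiles 91.3, 90.5 and 91.3, and oligodendrocyte lineage and cortical markers at 22.6 and 23.5.

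D1 CC contained 79.2% (78.9 to 79.5%) of the D2 CC peaks, and D2 CC 73.0% (72.7 to 73.3%) of the D1 CC peaks. D2 peaks with none in D1 lay in the glypican gene Gpc5 (chromosome 14, 115759151 to 115759749, fold 8.73), Lcorl (8.39), Fgf13 (7.88) and the transcription factor gene Npas3 (7.59), each a gene-body peak. Of the 10 D2 peaks named, 3 were held by exactly the patch-poor lists. All 10 D1 peaks named, Zfp97 and Kif11 among them, were held by exactly the patch-rich lists. These include D2 CS and leave out D1 SS, so the 10 peaks followed the technical set and not the cell type. Among equally long lists, the D2 markers stayed at percentile 0.00, while the microglia markers lay at 50, the adhesion genes at 18.6 and the immediate-early genes at 85.0. Ties alone can give the value of 50, which tells little about the microglia markers. With 50 kb on each side counted, the delayed genes lay at 10.8.

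The strongest 10000 peaks of the longer list, ranked by the authors' q, were searched in the shorter list of each pair. D2 CS held 93.3% (92.8 to 93.8%) of those of D2 SS and 91.7% (91.2 to 92.3%) of those of D2 CC, and D1 SC held 92.6% (92.1 to 93.1%) of those of D2 SC and 94.1% (93.7 to 94.6%) of those of D1 SS. D1 SS held 96.2% of those of D1 CS, 96.9% of those of D1 CC and 98.96% of those of D2 SS. Shares in the other pairs were 98.7% (D1 CC in D2 CC), 99.04% (D1 CC in D1 SC), 99.3% (D1 CS in D2 CS), 99.9% (D1 CC in D1 CS), 99.99% (D2 SS in D2 SC) and 100% (D2 CC in D2 SS and in D2 SC).

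Over the 14 comparisons, 45 of 252 percentiles lay outside the central 95%, where evenly spread percentiles would give 12.6. That figure is only a guide, since tied lists cannot fall outside and the comparisons reuse the same 8 lists. At equal list length 15 of these 45 stayed outside on the same side, 28 moved inside and 2 reversed, and 22 others came to lie outside. The 6 lists never outside were pan-MSN genes (percentiles 17.1 to 95.3), dopamine and cAMP signalling (29.1 to 88.0), cocaine-linked regulators (5.23 to 96.0), the machinery of the histone variant H2A.Z (15.2 to 96.5), vascular markers (31.8 to 90.5) and striatal interneuron markers (16.1 to 91.3). Vascular and interneuron markers had a median of 0 in several comparisons, as in D1 SC over SS (percentiles 47.3 and 49.7), where most members had no peak in either list. Ties with matched lists kept such percentiles away from the limits, so these comparisons tell little about those markers. Some of the 28 percentiles that moved inside at equal length may also have done so by ties, which were not counted. Within a technical set 18 of 126 percentiles lay outside, and across sets 27 of 126, where evenly spread percentiles would give 6.3 in each.

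**Figure D4:**
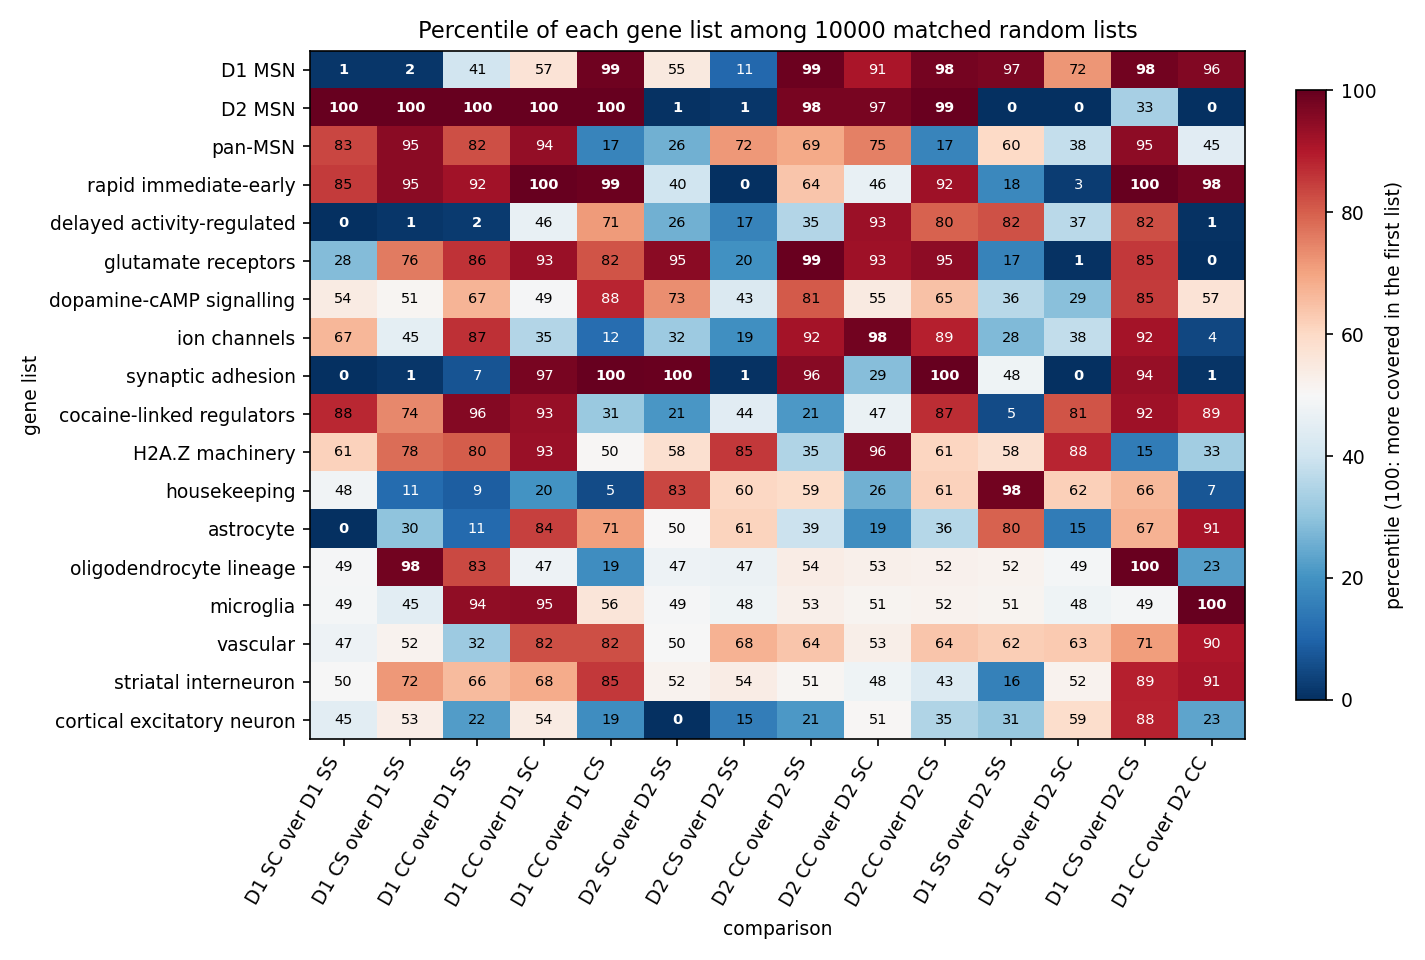
Each cell gives the percentile of a gene list (rows) in a comparison (columns) among 10000 matched random lists, with 100 meaning more covered in the first list named and 0 less. Bold white values lie outside the central 95%: the D2 MSN markers stand at 0.00 in D1 SS over D2 SS and at 100 in D1 SC over D1 SS.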

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

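Peaks on patch scaffolds lie outside the measurements compared above. They numbered 4 in D1 SS, 74 in D1 SC, 115 in D1 CS, 144 in D1 CC, 7 in D2 SS, 7 in D2 SC, 71 in D2 CS and 7 in D2 CC. The tests of background depth, enrichment, relapse, list length, nuclei of other cells and gene copies were chosen after the results they concern were seen, while those of patch sequences, gene-dense chromosomes and D2 nuclei were written before.

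The D1 CC list was 2.70 times as long as the D1 SS list. The tables argue against background read depth as the source, since the background of D1 CC was 1.03 times that of D1 SS. Higher enrichment at all open regions may contribute, but the widths of regions cannot decide it. The regions in all 8 lists were wider in D1 CC than in D1 SS by a median ratio of 1.45, with more bases in 98.9% of them. The ratio to D1 SS was also 1.36 in D2 CC and 1.31 in D2 SS, other long lists, and 1.07 in D2 CS, the shortest. Width and list length come from the same peak calls, so the ratio is not separate evidence of enrichment. Relapse itself stays open: the D2 CC list was 1.11 times as long as D2 SS, but D1 and D2 MSNs need not respond alike, and D1 CC and D1 SS differ in technical set. D1 CC was also 2.72 times as long as D1 SC within a set, where the background of D1 SC was the lowest of the 8.

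The 4 patch-rich lists stand apart from the other 4 by a split that matches neither cell type nor state but follows the library numbers (4 or 8 against 1 or 2) and the order of the labels, and no biological explanation was tested. A bias toward gene-dense chromosomes is consistent with the split, with a Spearman rho of 0.870 between gene density and the ratio of peak shares over the 19 autosomes (at least 0.847 without any 1, and 0.831 without chromosomes 7 and 18), though chromosome shares were among the features in which the split was seen, so this describes it more than it explains it. Reads shared with patch sequences could not be weighed, since patch peaks carry 0 gene names and the test value of 0% was fixed by that. Reads shared between near-identical gene copies stay open, because 13.2% of the regions in the patch-rich lists alone were nearest to a Zfp or Gm gene, against 3.33% of the regions in all 8 lists, between the bounds set for the test. A difference in batch, in the number of libraries per list or in the processing of reads may lie behind these values, and they cannot be told apart here.

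D2 MSN marker genes held peaks in D1 SC that D1 SS lacked. List length is argued against in D1 SC, whose list was 0.991 times as long as D1 SS, and stays open in D1 CC, where the percentile was 19.9 at equal length but strong D2 regions absent from D1 SS had a median fold rank of 84.1%. Nuclei of cells other than MSNs stay open: 18 of 61 of their markers had a peak in D1 SC and 19 in D1 SS, a ratio of 0.947, but weak peaks were less detectable in D1 SC. D2 nuclei among the D1 nuclei may be a source: of 338 strong D2 regions absent from D1 SS, 64.8% were found in D1 SC, 90.5% in D1 CS and 99.7% in D1 CC. The same value would arise had D1 SS alone lost sites, and 2366 regions were in every list except D1 SS (2239 for D2 CS and 1361 for D1 SC, other short lists), so a mixture of nuclei, a loss in D1 SS and opening of D2 sites after cocaine stay open, as does the technical set.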

How the results depend on the processing

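The alternatives with a fold of at least 6 and within a technical set were chosen after the data were seen, and the others before. No paired analysis was possible because each group has 1 list with no column per library. For the same reason the replicate block and leaving out each replicate were not run, and the motif windows of 100 bp and motifs at equal length were not run because no genome was used. Depth limits weak sites most in D1 SC, with a background of 1.15 reads. Peak numbers were lower by less than 1.5 times on autosomes (27211 to 75289) and at a q of at most 1e-05 (22216 to 65178), and overlap shares on autosomes stayed within their intervals. Of the 45 gene list percentiles outside the limits, 43 stayed outside on the same side with the larger pseudocount, 30 with 50 kb on each side and 15 at equal length, where 28 moved inside and 2 reversed. The cause was not tested for any value below, except that equal length, by its construction, removes the weaker peaks of the longer lists.

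With promoters within 2.5 kb, the promoter share was 42.5% in D1 SS, 51.0% in D1 SC, 39.4% in D1 CS, 29.6% in D1 CC, 30.1% in D2 SS, 30.2% in D2 SC, 54.0% in D2 CS and 28.4% in D2 CC. At equal length it was 44.6% in D1 CS, 42.3% in D1 CC, 37.8% in D2 SS, 36.5% in D2 SC and 36.4% in D2 CC, and within its interval in the other lists.

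The share of the shorter list found in the longer is given in the order D1 SC in SS, D1 SS in CS, D1 SS in CC, D1 SC in CC, D1 CS in CC, D2 SC in SS, D2 CS in SS, D2 SS in CC, D2 SC in CC, D2 CS in CC, D1 SS in D2 SS, D1 SC in D2 SC, D2 CS in D1 CS and D2 CC in D1 CC. A reciprocal overlap of 50% gave 54.1, 64.9, 67.3, 58.7, 64.7, 74.0, 55.6, 76.6, 76.9, 53.9, 72.2, 61.0, 62.0 and 63.2%. A peak within 1 kb gave 77.1, 88.5, 97.9, 99.3, 95.6, 89.3, 95.01, 91.4, 93.3, 95.2, 98.5, 94.2, 96.1 and 82.0%. A fold of at least 6 in the shorter list gave 89.2, 98.8, 99.9, 99.7, 99.9, 99.9, 97.9, 99.97, 99.99, 97.8, 100, 97.1, 99.7 and 98.0%. Because fold is not scaled between lists, this cut kept 5715 of 28579 peaks in D1 SS but 14264 of 28321 in D1 SC. These shares therefore cover unlike parts of the lists. From the second pair on, a q of at most 1e-05 gave 88.1, 98.2, 99.3, 95.9, 88.6, 95.6, 91.8, 93.7, 96.0, 98.8, 94.1, 95.7 and 78.8%, and equal length 73.6, 78.5, 84.6, 85.3, 87.9, 77.2, 87.8, 88.0, 75.4, 82.8, 74.7, 82.5 and 77.3%.

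Of the strongest 5000 peaks in place of 10000, D1 SC held 98.3% of those of D1 SS, 99.9% of D1 CC and 98.0% of D2 SC, D1 SS held 98.4% of D1 CS, 98.6% of D1 CC and 99.9% of D2 SS, D1 CS held 100% of D1 CC, D2 SC held 100% of D2 SS, D2 CS held 98.5% of D2 SS, 97.7% of D2 CC and 99.98% of D1 CS, and D2 CC held 99.02% of D1 CC. Ranked by fold, D1 SC held 91.5% of D1 SS, 90.7% of D1 CC and 84.6% of D2 SC, D1 SS held 94.2% of D1 CS, 90.5% of D1 CC and 96.1% of D2 SS, D1 CS held 98.7% of D1 CC, D2 CS held 85.3% of D2 SS, 79.7% of D2 CC and 96.9% of D1 CS, and D2 CC held 98.2% of D1 CC.

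Gene lists outside the percentile limits numbered 47 of 252 with the larger pseudocount, 54 with 50 kb on each side and 39 at equal length, and 18 within a technical set. With 50 kb there were 3 in D1 SC over SS, 7 in D1 CC over CS, 6 in D2 CS over SS, 5 in D2 CC over SS and 2 in D2 CC over SC. At equal length there were 3 in D1 CS over SS, 4 in D1 CC over SS, 2 in D1 CC over CS, 1 in D2 SC over SS and 0 in D2 CC over SC. With a pseudocount of 1000 bp there was 1 in D1 SS over D2 SS. At equal length the D2 MSN markers reversed to percentile 0.24 in D1 CC over SC, and glutamate receptors to 0.275 in D2 CC over SS.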

Other observations

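These values were chosen after they were seen, and no test was run on them. Oligodendrocyte genes differed between the D1 lists: Mog, Mag, Mobp and Sox10 held peaks in D1 CS (395, 409, 246 and 205 bp) and D1 CC (218, 431, 698 and 709 bp) and in no other list. Mbp, the myelin basic protein gene, was covered in all 8, from 1821 bp in D2 CS to 8004 bp in D1 CC. Markers of other cell types with a peak numbered 41 of 61 in D1 CS and 50 in D1 CC, against 24 to 36 in the D2 lists.

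Among cortical excitatory neuron genes, Neurod6 had a peak of 588 bp in D2 CS alone, and Tbr1 had 829 bp in D2 CS against 487 bp in D2 SS and 544 bp in D2 CC. The immediate-early gene Ier2 had peaks in D1 CS (496 bp), D1 CC (1069 bp) and D2 SC (229 bp) and in no other list. Within 150 kb of Drd1 there were 16, 13, 21 and 39 peaks in D1 SS, SC, CS and CC and 9, 8, 5 and 12 in the D2 lists. Within 150 kb of Drd2 there were 2, 8, 16 and 15 in the D1 lists and 23, 27, 18 and 31 in the D2 lists.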
